A study of Drosophila melanogaster with 4 samples.

How the data were processed

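The samples were whole embryos of Drosophila melanogaster, of a yellow, cinnabar, brown, speck strain, at 16 to 24 h of development. Per the labels' protocols, the eggs were laid over 8 h and the embryos were cross-linked for 15 min in 1.8% formaldehyde. Chromatin was then immunoprecipitated with a rabbit polyclonal serum raised against the N-terminal part of Pangolin, the fly TCF protein. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) recovers the DNA fragments cross-linked to a protein. The series has 2 ChIP libraries and 2 libraries of input DNA, which is chromatin that was not immunoprecipitated and serves as background.

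The submitters' processing notes name CASAVA 1.7.0.2 and 1.7.0.3, the aligner BWA, the peak caller MACS2 and the genome build BDGP5, with no role or order. The deposited file is 1 peak list for the whole series, in FlyBase release 5 coordinates per the file headers. Each line gives a peak's sequence, start, end and a score that the authors deposited with it. The scale of that score, the calling threshold and the way the replicates were combined are not given in the sources used here. The score was therefore used mainly to describe, rank and filter peaks within this list, and was read neither as a fold enrichment nor as a probability. Among the closing observations, scores were also multiplied by factors and matched for equal values. The multiplication treats the score as a ratio scale, which the sources used here do not state. No column names a library. Depth per library is unknown, no value has a replicate error, and nothing can be said of the agreement between the replicates. All p-values below compare peaks within 1 list, and peaks are not independent replicates of the experiment. Whether the ChIP samples came from separate embryo collections is not stated in the labels.

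Peak width was computed as end minus start plus 1, and the midpoint stood for the peak's position, since no summit is listed. Peak density was computed on the 6 chromosome arms X, 2L, 2R, 3L, 3R and 4. Arm lengths of this build were not used here, so each arm's extent was taken from its first to its last listed peak, in place of the arm length planned before the data were examined. Each arm's share of the peaks was compared with its share of the summed extents by a two-sided exact binomial test, with Benjamini-Hochberg adjustment over the 6 arms. Densities carry exact Poisson 95% intervals, shares exact Clopper-Pearson intervals, and ratios of densities exact conditional binomial intervals. These cover counting error of peaks only. Clustering was measured as the share of peaks with another midpoint within 10 kb, and as the largest number of peaks in 100 kb. Both were compared with 1000 random placements of the same number of peaks within each arm's extent, one-sided, where 0.001 is the smallest p that can be reached. Medians and correlations were compared by two-sided permutation tests with 100000 resamples, where 1e-05 is the smallest p. The ratio of the density on X to that on the 4 autosomal arms together, the comparison of their scores, the comparison of scores between peaks with and without a neighbour, the joining of peaks into groups with gaps of up to 10 kb and the search for long stretches without peaks were added after the data were seen.

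The planned tests of peak position relative to genes, of gene lists (Wnt pathway members, known wingless targets, Hox genes and others) and of TCF binding motifs were not run. They need genes or sequence in release 5, while the gene table at hand is of release 6, and coordinates were not carried between builds. Genes at the peaks are therefore not named. The rule for naming set before the data were examined falls back in that case on the 15 highest-scoring peaks by position. The largest groups of peaks and the longest stretches without a peak were named after their values were seen.

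The alternatives were the top 50% and the top 25% of the peaks by score, neighbour distances of 5 and 20 kb, counting the unplaced sequences U and Uextra, and 5 added later: the large autosomal arms alone, extents counted from base 1, groups of peaks counted once, merging peaks under 1 kb apart, and a score of at least 50. The density and clustering tests were checked on simulated peaks, with 20 runs per setting and 1325 peaks in each run before X was thinned. With the number of peaks on X cut to 50%, X was called lower in 20 of 20 runs, with a mean ratio of 0.492 to the large autosomal arms. The test was given the extents used in the simulation, so this ratio follows from the setting. The taking of extents from the first to the last peak was not checked. With evenly placed peaks, any arm was called in 2 of 20 runs and clustering in 0 of 20. No close pairs were added in those runs, so false calls of the arm test among clustered peaks were not checked. Clustering was called in 20 of 20 runs with 20% of the peaks placed in close pairs. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.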

Results

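The binding of Pangolin, the Drosophila TCF protein, was mapped by ChIP-seq in embryos of 16 to 24 h. Pangolin is a DNA-binding protein of the HMG-box family that acts with Armadillo, the fly beta-catenin, in transcription downstream of the Wnt ligand Wingless. The design sets 2 ChIP libraries against 2 input libraries at a single stage, and the question it addresses is where on the genome anti-TCF ChIP DNA exceeded input DNA. The deposited answer is 1 list of 1355 peaks on 11 sequences of FlyBase release 5, numbered without gaps. The depth of the libraries is unknown and the peaks carry no value per replicate.

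The peaks lay almost entirely on the 6 main chromosome arms, which held 1325 of them, against 30 (2.21%) elsewhere. Arm 3R carried 327 peaks, 3L 310, 2L 300, 2R 243, X 139 and the small chromosome 4 only 6. The peaks were narrow, with a median width of 379 bp (interquartile range 259.5 to 644 bp) and a range from 201 to 2701 bp. On the 6 arms they covered 684 kb, or 0.590% of the summed extents. Scores were strongly skewed. The median score was 14.25 (interquartile range 10.34 to 26.69), 65.7% of peaks scored under 20, and 82 peaks reached 100 or more, up to 458.

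**Figure D1:**
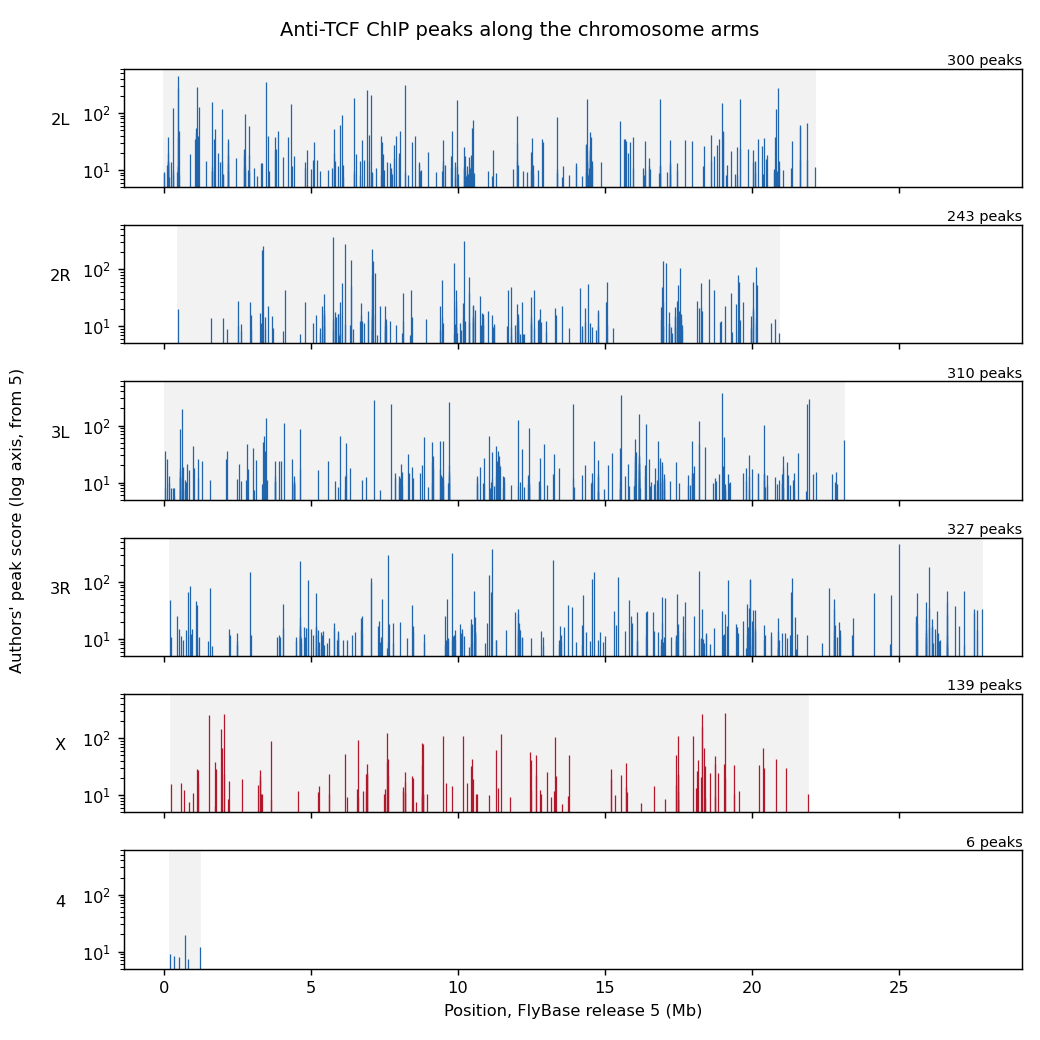
Position of each peak on the 6 chromosome arms (x axis, Mb, FlyBase release 5) and its score in the authors' list (y axis, log scale from 5). Each vertical line is 1 peak, X is in red, the grey band runs from the first to the last peak of the arm, and 2R shows a peak-free stretch of 1.63 Mb that begins at 15260313.

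The arms of chromosomes 2 and 3 held all of the 15 highest-scoring peaks. Of these, 5 lay on 2L, 4 on 3L, 4 on 3R and 2 on 2R, while the highest peak on X scored 277 and fell just short of the 15. The highest peak of the genome was on 3R, from 24982898 to 24984424, with a score of 458. A peak on 2L from 480409 to 481494 scored 453, and a second one of the 15 lay within the same 20 kb, from 470138 to 471309, with a score of 278. The next 3 were at 3R from 11168468 to 11170180 (score 378), at 2R from 5747480 to 5749604 (score 371) and at 3L from 18988437 to 18989805 (score 367).

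The other 9 ranged in score from 281 to 349. On 3L these were the peaks from 15527694 to 15528595, from 21946960 to 21948192 and from 7126910 to 7127697. On 2L they were the peaks from 3476429 to 3478303, from 8204889 to 8205654 and from 1119061 to 1120399. On 3R they lay from 9809092 to 9809799 and from 7603882 to 7605213, and on 2R from 10194900 to 10195843. All 15 were wider than the median peak, from 708 to 2125 bp. Over all 1355 peaks, score and width rose together, with Spearman's rho of 0.77 and Pearson's r of 0.55 (permutation p = 1e-05 for both, the smallest possible). Spearman's coefficient was 0.63 in the top 50% and 0.41 in the top 25% of the peaks by score. Within the 5 large arms rho lay between 0.76 on 3L and 0.80 on X. These are correlations across peaks, not across samples.

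Peaks were sparser on the X chromosome than on any of the 4 large autosomal arms. X carried 6.42 peaks per Mb (95% interval 5.40 to 7.58), against 11.8 on 3R, 11.9 on 2R, 13.4 on 3L and 13.5 on 2L. Relative to the 4 autosomal arms together, at 12.7 peaks per Mb, the density on X was 0.507 times as high (95% interval 0.422 to 0.605). Against single arms the ratio ranged from 0.474 for 2L to 0.542 for 3R. X held 10.5% of the peaks and 18.7% of the summed extents (exact binomial test, adjusted p = 2.1e-15). These intervals and tests count each peak as independent, although many peaks lay close together. With groups of peaks counted once, the density on X was 0.574 times that on the 4 autosomal arms (95% interval 0.464 to 0.705, exact binomial test, p = 1.4e-08). The share of groups on X was then 0.626 times its share of the extents (exact binomial test, adjusted p = 1.1e-07).

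With all peaks counted, the 4 large autosomal arms did not differ detectably from one another. Taken alone, they gave ratios of the share of peaks to the share of the extents of 1.07 for 2L, 1.06 for 3L, and 0.940 and 0.936 for 2R and 3R (exact binomial test, adjusted p = 0.29 for each). Over all 6 arms, where the low share of X raises the ratios of the others, 2L and 3L were called higher, at 1.19 and 1.17 times (exact binomial test, adjusted p = 0.0039 for each), and 2R and 3R, at 1.04 times each, were not (adjusted p = 0.49 for each). Over the 6 arms the ratio of 2L was 1.19 in the top 50% of the peaks, not called (exact test, adjusted p = 0.066), and 1.39 in the top 25%, called (adjusted p = 0.0065). That of 3L was 1.08 in the top 50% (exact test, adjusted p = 0.42) and 0.964 in the top 25%, and 2R and 3R were also under 1 in the top 25%, at 0.896 and 0.962. In the top 25%, 2L held 86 peaks on 22.1 Mb, 2R 51 on 20.4 Mb, 3L 62 on 23.1 Mb and 3R 74 on 27.6 Mb. The low share of X therefore does not account for the lead of 2L there, but the 4 arms were not tested alone in this subset. Chromosome 4 had 5.87 peaks per Mb, with an interval of 2.15 to 12.8 that holds the densities of X, 2R and 3R, and a ratio of 0.513 over the 6 arms (exact test, adjusted p = 0.16). With extents counted from base 1 its ratio was 0.433 and called (exact test, adjusted p = 0.045), and it had 1 peak in the top 50% (ratio 0.174) and 0 in the top 25%, neither called.

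The shortfall on X was larger among the lower-scoring peaks. Of peaks scoring under the list's median, X had 2.35 per Mb and the 4 autosomal arms 6.60, a ratio of 0.356 (95% interval 0.262 to 0.475). In the top 50% the ratio was 0.672 (0.530 to 0.842), and in the top 25% it was 0.789 with an interval of 0.571 to 1.07, where X was no longer called lower (exact binomial test, p = 0.13). Scores under the list median made up 36.7% of X peaks and 52.2% of autosomal ones (Fisher's exact test, two-sided, p = 0.00062). With groups of nearby peaks counted once by their highest score, these shares were 32.4% and 41.4%, and the difference was not called (Fisher's exact test, p = 0.090). The median score was 19.8 on X and 13.6 on the autosomal arms, a difference of 6.26 (95% bootstrap interval 2.46 to 9.94, permutation p = 2e-05). The difference from each autosomal arm taken singly was between 5.83 and 6.30, with adjusted permutation p from 0.0001 to 0.0031. With groups counted once by their highest score, the medians were 23.5 on X and 16.8 on the autosomal arms. That difference, 6.74, was called (permutation p = 0.005). X peaks were wider, with a median of 446 bp against 376 bp (permutation p = 0.022). Score and width rose together on X (Spearman's rho 0.80), and widths were not compared at equal score.

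**Figure D2:**
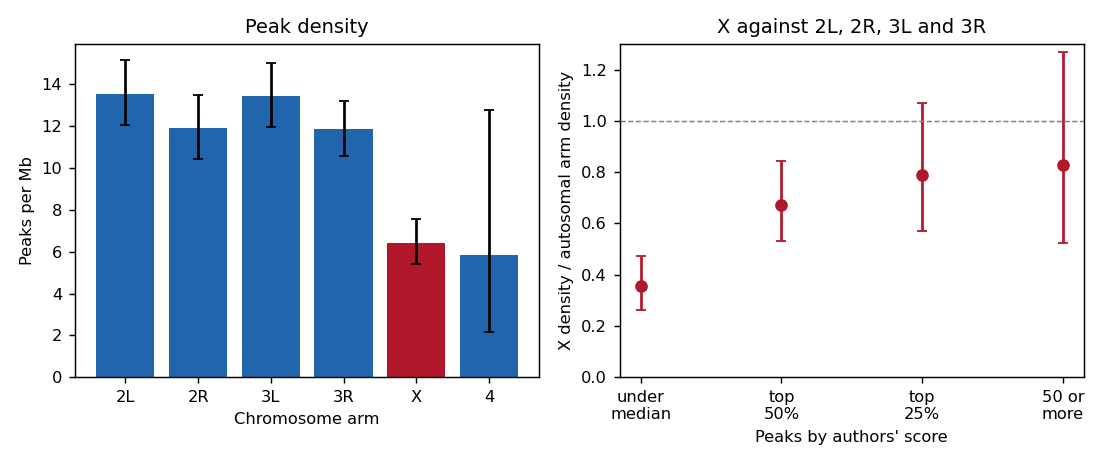
Left, peaks per Mb on each chromosome arm, with X in red and exact Poisson 95% intervals as bars, from 5.87 on chromosome 4 and 6.42 on X to 13.5 on 2L. Right, the density on X divided by that on 2L, 2R, 3L and 3R together, for peaks sorted by the authors' score, with exact 95% intervals: the ratio is 0.356 under the median score and 0.829 at a score of 50 or more, and the dashed line marks equal density.

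The peaks lay in groups. Of the 1325 peaks on the arms, 663 (50.0%) had another peak within 10 kb, where random placement within the arms gave 21.2% ± 1.46 (SD, 1000 placements) and at most 25.7% (permutation test, one-sided, adjusted p = 0.001, the smallest possible). The share was higher than in every random placement on each of the 5 large arms, from 38.1% on X to 53.5% on 2R. On chromosome 4 none of the 6 peaks had such a neighbour. The random placements were uniform along each arm and took no account of where genes or alignable sequence lie.

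Joined at gaps of up to 10 kb, the arm peaks formed 898 groups, of which 651 were single peaks and 159 were pairs. Another 20 groups held 5 or more peaks each, together 131 peaks. The largest groups had 10 peaks each. One lay on 2R from 7065950 to 7092179, with a highest score of 231, and the other on 3L from 16142489 to 16159388, with a highest score of 160. A group of 9 on 3R, from 12050613 to 12087854, was made of peaks that scored at most 33.9. The group of 8 on 2L from 470138 to 489805 contained both of the high-scoring 2L peaks named above, and a further group of 8 lay on 3R from 4633747 to 4648595, with a highest score of 233. The group with most peaks on X had 7, from 8778027 to 8799346.

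The densest 100 kb of the genome held 12 peaks, on 3R from 12033569 to 12106538, against 7.10 ± 0.780 (SD) in the densest window of the random placements (permutation test, adjusted p = 0.001). In the top 25% of the peaks the densest window had 5, which was not called (permutation test, adjusted p = 0.072). With peaks under 1 kb apart merged, the densest window had 9, against 6.51 on average and at most 10 in the random placements (permutation test, adjusted p = 0.016).

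**Figure D3:**
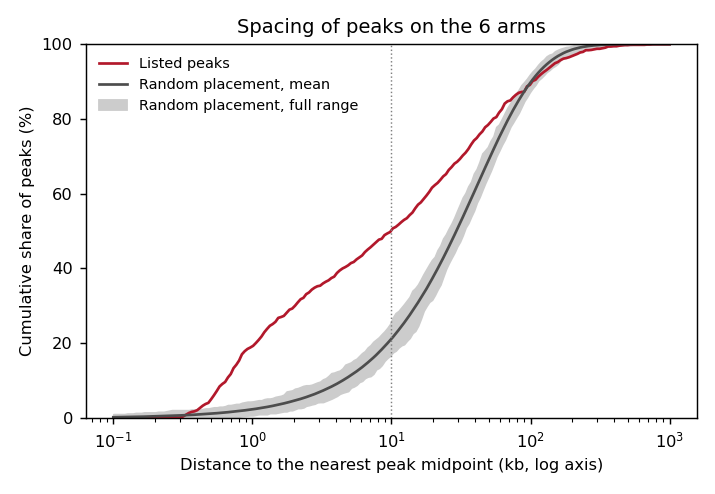
Cumulative share of peaks on the 6 arms (y axis, %) by distance to the nearest other peak midpoint (x axis, kb, log scale). The red line is the listed peaks, the dark line and grey band are the mean and full range of 1000 random placements, and at 10 kb (dotted line) the listed peaks reach 50.0% and the random mean 21.2%.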

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

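The following signals lie on sequences that the comparisons between chromosome arms left out, and their tests were chosen after the values were seen. The collection of unplaced fragments Uextra held 20 peaks and the unplaced sequence U held 5. Over their extents from first to last peak these were 0.707 and 1.06 peaks per Mb, under the density of each of the 6 arms. Together these 25 peaks had a median score of 28.3, against 13.9 on the 6 arms, a difference of 14.4 (95% bootstrap interval 4.74 to 24.1, permutation p = 0.0018). Their median width was 378 bp, against 379 bp on the arms. None of the 25 reached a score of 50, the highest being 46.2 on Uextra from 5307339 to 5307846, while 161 arm peaks (12.2%) did (Fisher's exact test, p = 0.063). The heterochromatic sequences 2RHet and 3RHet had 2 peaks and 1 peak. The mitochondrial genome had 2 peaks, from 2510 to 2768 with a score of 12.0 and from 14203 to 14464 with a score of 22.9, although Pangolin is known as a nuclear protein.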

How the results depend on the processing

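Of 51 alternative values for 12 results, 32 kept both direction and side of the threshold, including every alternative for the share of peaks with a neighbour (13.6% to 32.9% at 10 kb, 41.1% at 5 kb, 62.0% at 20 kb) and for the correlation of score and width (rho 0.63 in the top 50%, 0.41 in the top 25%). No paired analysis was possible because the list carries no value per library, and leaving out a replicate was not possible for the same reason. Not run for want of a genome of this build were the arm lengths without N bases and random placement near gene starts. As ratios of the share of peaks to the share of the extents, the top 50% of the peaks gave 1.19 for 2L and 1.08 for 3L, no longer called, and 0.991 for 3R, turned. The top 25% gave 1.39 for 2L, called, 0.829 for X, no longer called, and 0.896 for 2R, 0.964 for 3L and 0.962 for 3R, turned. The large autosomal arms alone gave 1.07 for 2L and 1.06 for 3L, no longer called, and 0.940 for 2R and 0.936 for 3R, turned, because X is left out of the shares. None of the turned values was called (exact binomial test, adjusted p of 0.29 or more). The main ratios of 2R and 3R were not called either. Counting U and Uextra gave 1.31 for 2R and for 3R, newly called, because these sequences add extent with few peaks. Groups counted once gave 1.13 for 3L, no longer called, and extents from base 1 gave 0.433 for chromosome 4, newly called. The density of X relative to the 4 autosomal arms was 0.789 in the top 25% and 0.829 at a score of 50 or more, neither called. The densest 100 kb of the top 25% held 5 peaks, no longer called. Merging peaks under 1 kb apart left a median score difference between peaks with and without a neighbour of -1.36, no longer called. The top 25% leaves 323 arm peaks and the groups number 898, fewer than the 1325 tested, and the causes were not otherwise tested. The values from the autosomal arms alone, from extents counted from base 1, from groups counted once, from merging and from a score of 50 or more were chosen after the data were seen.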

Other observations

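In this part, the tests on X scores and densities, the length of the 2R stretch, the merging and group counts, the scores of peaks with and without a neighbour and the scores of adjacent peaks were chosen after the result was seen. A long part of 2R was without peaks. Between 15260313 and 16886407, 1.63 Mb, no peak was listed, where the arm's mean density would place 19.3 peaks in 12.8 groups. The second longest stretch on 2R, from 484555 to 1586866, was 1.10 Mb, and the longest on X was 1.41 Mb, from 13785388 to 15193817. The longest on 3L was 0.951 Mb, on 3R 0.883 Mb and on 2L 0.647 Mb.

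The 2R stretch was set against 2 explanations. Random spacing of peak groups gave a longest stretch of 0.715 Mb on average and 1.46 Mb at most in 1000 placements (permutation p = 0.001, adjusted over the 6 arms 0.006), so its 1.63 Mb was longer than such spacing gave, and on no other arm was the longest stretch called by this test (adjusted p from 0.11 to 0.40). With single peaks placed at random, which ignores their grouping, the longest stretch was called on all 5 large arms (adjusted permutation p from 0.003 on 2R and 3L to 0.046 on 2L). A loss of listed peaks from the file remains open: 0 peak numbers were skipped, since peak 483 ended before it and peak 484 began after it, but peaks may have been numbered after such a loss. High input signal, low alignability and a true lack of sites in this part of 2R were not tested.

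The shortfall of peaks on X has a candidate explanation in detection, since embryos of mixed sex carry fewer copies of X than of the autosomes, and the labels give no sex. If one factor lowered every X score and peaks under the listed minimum were lost, X scores would lie at or under the autosomal ones. They lay 6.26 above at the median. Autosomal scores multiplied by factors from 0.3 to 0.95 and limited to the list's range had medians of at most 12.9, against 19.8 on X. Mild factors also removed few peaks: a factor of 0.75 kept 96.4% of the autosomal peaks. Among the factors tried, 0.4 came nearest to the density ratio of X, keeping 46.5%. These values argue only against a single multiplying factor of the score as the whole cause. The scale of the score is unknown and no other form of lowering was tried, so lower detection on X stays open. If only X sites near the caller's threshold were missed, peaks at or above the list's median score would be about as dense on X as on the autosomal arms. Their ratio was 0.672 (95% interval 0.530 to 0.842), which argues against a loss confined to scores under the list's median as the whole cause. The ratio was 0.789 (0.571 to 1.07) in the top 25% and 0.829 (0.523 to 1.27) at a score of 50 or more. Both of these intervals hold 1 and also 0.672, so they do not show equal density. A loss that reaches above the median score stays open, as do fewer sites on X. No biological explanation was tested.

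Most scores may have been computed against a single genome-wide background, since 80.6% of X scores equalled, to 2 decimals, a score of an autosomal peak, against at most 15.1% after shifting the X scores by 0.01 to 0.1. Over the whole list, with 453 distinct scores, 1035 peaks (76.4%) shared their score with another peak, and the score 10.65 occurred 34 times. Any cause that confines scores to a common set of values would give such matches, so they do not identify the background used. A total of 45 peaks had the minimum width of 201 bp.

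The grouping of peaks could come from wide bound regions listed as several peaks. Merging peaks under 1 kb apart removed 200 of 1325 peaks, and 32.9% of the rest still had a neighbour within 10 kb. Random placement gave 18.2% on average and at most 22.3% in 1000 placements, which argues against splitting at this scale as the whole cause. Before merging, the share was 50.0%, against 21.2% on average at random. The excess over random placement was thus smaller after merging, and splitting as a part of the cause stays open. Uneven spacing of genes and open chromatin along the arms stays open, untested without an annotation of this build. Peaks with a neighbour scored slightly lower than lone ones, with medians of 13.5 and 14.6 (difference -1.11, permutation p = 0.036), and after merging the difference was -1.36 and not called (permutation p = 0.13). The hypothesis that adjacent peaks within 10 kb have like scores was tested over 419 pairs. Spearman's rho was -0.053 (95% bootstrap interval -0.15 to 0.05, permutation p = 0.28) and Pearson's r of log2 scores was -0.08 (permutation p = 0.093). A peak with neighbours on both sides enters more than 1 pair, while the interval and tests take pairs as independent. With that limit, the values leave room for no more than a weak positive relation.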
